A study of Homo sapiens with 12 samples.

How the data were processed

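The data came from 12 Affymetrix U133 Plus 2.0 arrays of 22Rv1, an established human prostate carcinoma cell line. Per the labels' protocols, total RNA was extracted with a column kit and amplified by in vitro transcription from the 3' end of messages before hybridisation. The labels place 3 arrays in each of 4 groups: vehicle, and 4 h, 6 h or 16 h with a small compound that the series title describes as an ONECUT2 inhibitor. The vehicle arrays carry no treatment time in the labels, and the titles of the 16 h arrays lack 1 code element, of unstated meaning, that the other 9 titles carry. Compound, time in culture and anything else that differed between those titles therefore cannot be separated in any comparison with the 16 h arrays. Nothing in the labels says whether the replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.

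The authors deposited log2 values for 54675 probe sets on each array. GCRMA, a method that corrects background by probe sequence, normalises arrays to each other and summarises the probes of a probe set, is named in the submitters' processing notes without a version. The deposited log2 values ran from -0.49 to 13.77, and the median of each array lay between 2.1 and 2.15. No scanner files were used here. The number of arrays limits the precision, and a signal near the level of unspiked bacterial control probe sets, whose highest value per array averaged 2.14 on the vehicle arrays, carries little information. Because such a normalisation gives all arrays nearly the same distribution, a change shared by most genes would not be visible in these values.

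Gene names came from the platform annotation given with the data and were updated through the Entrez gene identifier against a RefSeq gene table. Of the probe sets, 41097 had 1 symbol, 1801 had several, and 11777 were not listed and stayed unnamed. After 62 control probe sets were set aside, 41091 probe sets named 19775 genes, with 41037 symbols found through the RefSeq table and 54 kept as annotated. No genome build is given in the sources used here, so no coordinates are reported. A gene was represented by its probe set with the highest mean over the 12 arrays, termed its brightest probe set, and was tested where that mean was at least 2.11, the median over all probe sets. This left 12635 genes. The other probe sets of a gene are termed its second probe sets. Probe sets whose names end in _x_at or _s_at can bind transcripts of several related genes.

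All 12 arrays entered 1 linear model per gene with the 4 groups as factors, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom, 3.69 prior degrees of freedom). Each of the 6 comparisons between groups was tested two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 12635 genes. A gene is described as risen, fallen or changed where the adjusted p was below 0.05. Errors are the model's standard error (SE) of a log2 change, or the SD over 3 arrays. Where all arrays of a group were at or below the highest unspiked control on the same array, a fold is given as at least the ratio to that control. Single array measures were compared by exact two-sided permutation of the 6 arrays, which cannot go below p = 0.1.

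The 29 gene lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. The lists covered hormone response, lineage, stress, metabolism, growth and, for other cell types, fibroblast, leukocyte and endothelial genes. They were tested with camera, which compares a list's members with all other genes, at its preset correlation of 0.01, with the Benjamini-Hochberg adjustment over the 29 lists. The same test with a correlation estimated from the residuals, and fry, which asks whether the members move one way on balance, were run beside it. The naming rule took the 6 largest rises and 6 largest falls among changed genes whose arrays did not overlap, up to 4 changed members of each list with the largest changes, the 4 largest differences in each direction between 2 treatment times, and 10 genes in every case: ONECUT2, ONECUT1, ONECUT3, FOXA1, HOXB13, KLK3, PEG10, MYC, SYP and CHGA.

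On simulated data with the real genes' means and spreads, the fit of the 4 h comparison over 12635 genes recovered 76% of genes changed by 0.5 and 99.2% of genes changed by 1 on the log2 scale, with 5.1% false calls, over 20 runs. Noise was drawn from a normal distribution independently for each gene and array, so these shares do not give the error rate on the real arrays. Agreement between times was measured across genes and set beside 100 simulations of unchanged groups that shared a simulated vehicle group, with genes drawn independently. The alternatives were quantile normalisation, median centring of each array, no filter or a filter at the 75th percentile, the mean of a gene's probe sets, preference for probe sets outside the _s_at and _x_at classes, all probe sets, a trended and robust prior, array weights, the 6 arrays of the compared groups alone, the replicate number as a block, and leaving out each array in turn. A fit without the 16 h arrays, a count that required 2 probe sets of a gene to pass, and correlations over disjoint arrays were added after seeing the data.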

Results

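Gene expression was measured in 22Rv1 cells, a human prostate carcinoma line that grows without added androgen, after 4 h, 6 h or 16 h with a compound described as an inhibitor of ONECUT2, and in vehicle-treated cells. ONECUT2 is a homeodomain transcription factor. The comparisons ask which transcripts differ from vehicle at each time and which differ between times. Each group had 3 arrays. Across the 12635 tested genes, arrays of 1 group correlated at r of 0.9964 to 0.9982, and the 16 h arrays correlated with vehicle arrays at 0.9817 to 0.9873.

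RNA controls on the arrays differed with treatment time. The log2 difference between the 3' and 5' ACTB control probe sets was 2.80 ± 0.08 (SD, n = 3) on vehicle arrays and 4.09 ± 0.09 (SD, n = 3) on 16 h arrays, because the 5' signal was lower by 1.38 (exact two-sided permutation p = 0.1, the smallest possible). The same difference for GAPDH was -0.47 ± 0.02 and -0.43 ± 0.04. The 18S ribosomal RNA control signal was 9.62 ± 0.29 on vehicle arrays, 8.98 ± 0.14 at 4 h, 8.64 ± 0.19 at 6 h and 11.05 ± 0.10 at 16 h, each time with exact permutation p = 0.1 against vehicle. The 28S ribosomal RNA control signal differed from vehicle by -0.29 at 4 h, -0.34 at 6 h and 1.18 at 16 h. The 6 h array of replicate 3 had an ACTB difference of 3.38, against 2.71 and 2.97 on the other two 6 h arrays.

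**Figure D1:**
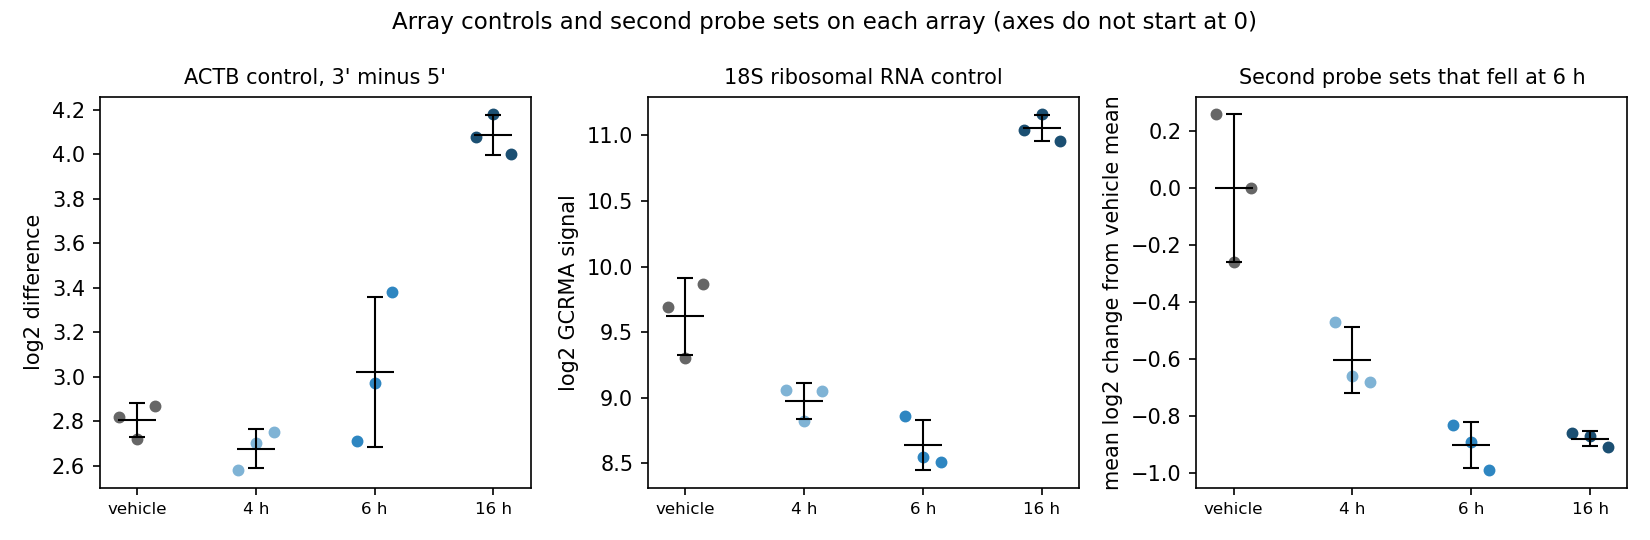
Points are single arrays (n = 3 per group), horizontal lines are means and bars are SD, on log2 axes that do not start at 0: the ACTB 3' minus 5' control difference, the 18S ribosomal RNA control signal, and the mean change of the 179 second probe sets that fell at 6 h relative to the vehicle mean. The 16 h arrays lie at 4.00 or above for ACTB, where the highest other array is at 3.38.

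At 4 h the largest rises were in HMOX1, KLF6, ATF3 and MAFF. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, rose 2.24-fold (log2 change 1.16 ± 0.14 SE, adjusted p = 0.0032, n = 3 per group). The transcription factor genes KLF6, ATF3 and MAFF rose 2.07-fold, 2.05-fold and 2.01-fold (log2 SE 0.11, 0.09 and 0.09). EPPK1 and NEDD9 rose 1.87-fold each. The largest fall was in BCL7A, 2.3-fold (log2 change -1.20 ± 0.19 SE, adjusted p = 0.019), followed by CYP1A2, ANGPTL4, SLITRK1, TMCC3 and IGFBP3, with falls of 1.69-fold to 1.5-fold.

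Among the 31 tested immediate early genes, which respond within minutes to hours to growth factors and stress, 6 rose and 1 fell at 4 h (14 and 1 adjusted over the list alone). KLF6, ATF3, EGR1 and CCN2 were the largest, with EGR1 up 1.78-fold and CCN2 up 1.73-fold. The list as a whole was shifted upward (camera adjusted p = 1.05e-12, and adjusted p = 0.312 with an estimated correlation). The gene that fell was MYC, by 1.32-fold (log2 change -0.40 ± 0.07 SE, adjusted p = 0.023). Under median centring 7 members rose and 0 fell, so this MYC call was lost. Of 34 amino acid and ATF4 stress genes, ATF3 alone rose (7 adjusted over the list alone), and the list was shifted upward (adjusted p = 3.25e-05, and adjusted p = 0.731 with an estimated correlation).

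The NRF2 antioxidant list had 1 riser of 23, HMOX1 (4 adjusted over the list alone), and an upward shift at adjusted p = 0.0341 (adjusted p = 0.791 with an estimated correlation). Of 21 cholesterol synthesis genes 1 rose (3 adjusted over the list alone), namely INSIG1, a sterol-sensing regulator, by 1.43-fold, and the list was shifted upward at adjusted p = 0.0252 (adjusted p = 0.731 with an estimated correlation). No member of the 24 endoplasmic reticulum chaperone genes or the 35 cytosolic ribosomal protein genes passed (0 and 1 adjusted over the list alone, the latter a fall). Both lists were shifted downward, at adjusted p = 0.0165 and 0.0449 (adjusted p = 0.242 and 0.791 with an estimated correlation). The ribosomal protein call was lost without vehicle replicate 1 (adjusted p = 0.478) and without 4 h replicate 2 (0.398), and under quantile normalisation (0.33) and median centring (0.203). The NRF2 call was lost without vehicle replicate 3 (0.125), 4 h replicate 1 (0.136) and 4 h replicate 3 (0.0997). The cholesterol synthesis call was lost without vehicle replicate 2 (0.0535), vehicle replicate 3 (0.135) and 4 h replicate 1 (0.081). Counting every alternative, these 3 calls were lost 11, 10 and 6 times. On the same arrays the 18S ribosomal RNA control signal was lower than on vehicle arrays by 0.64. Single members of other lists that rose were GDF15 by 1.74-fold, ELF3 by 1.69-fold, PTGER4 by 1.64-fold, TIPARP and DNAJB4 by 1.43-fold each and LPIN1 by 1.29-fold, while SPDEF fell 1.37-fold and KRT19 fell 1.27-fold. Of the lists that passed at 4 h, none held with an estimated correlation, and fry, which tests whether a list's genes move on balance one way and does not compare them with other genes, passed for immediate early and endoplasmic reticulum chaperone genes (adjusted p = 0.0137 and 0.0134). The other 23 lists did not pass, the lowest adjusted p being 0.0854 for oxidative phosphorylation genes.

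In all, 58 of 12635 genes changed at 4 h by limma with Benjamini-Hochberg adjustment, 42 up and 16 down, and 1366 had an unadjusted p below 0.05. The vehicle and 4 h arrays did not overlap for 18.3% of all tested genes, where chance gives 10%. Leaving out vehicle replicate 1 or 3 gave 31 or 25 genes, and leaving out 4 h replicate 1, 2 or 3 gave 25, 26 or 27. A trended and robust prior gave 136, array weights 89 and the 75th percentile filter 90.

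At 6 h, 4 genes changed. MAT2A, which encodes the catalytic subunit of S-adenosylmethionine synthetase, rose 1.45-fold (log2 change 0.54 ± 0.08 SE, adjusted p = 0.049, n = 3 per group), the stress-induced cytokine gene GDF15 rose 1.41-fold (0.50 ± 0.07, adjusted p = 0.049), and PTGS1 rose from a signal of 2.26, near that of the unspiked controls (adjusted p = 0.049). QRSL1, a mitochondrial amidotransferase subunit gene, fell 1.49-fold (log2 change -0.57 ± 0.07 SE, adjusted p = 0.026). No gene changed 2-fold or more on its brightest probe set.

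The 24 endoplasmic reticulum chaperone genes, which serve protein folding in the secretory pathway, were shifted downward at 6 h (median log2 change -0.09, adjusted p = 6.21e-07, and adjusted p = 0.00741 with an estimated correlation), with 0 members past the threshold over all genes and 5 falls adjusted over the list alone. The NRF2 antioxidant genes were shifted upward (median 0.04, 0 of 23 past the threshold, 6 rises adjusted over the list alone, adjusted p = 0.000408, and adjusted p = 0.662 with an estimated correlation). The immediate early genes were also shifted upward (median 0.11, 0 of 31 past the threshold, 2 rises adjusted over the list alone, adjusted p = 0.0226, and adjusted p = 0.888 with an estimated correlation). Their call was lost without vehicle replicate 1 (0.0897), vehicle replicate 2 (0.277), 6 h replicate 2 (0.0614) and 6 h replicate 3 (0.0852), with the mean of probe sets (0.134) and with probe sets outside the _s_at and _x_at classes (0.352). The other 26 lists did not pass, with a lowest adjusted p of 0.0634 for metallothionein and metal-response genes. The 18S ribosomal RNA control signal was lower than on vehicle arrays by 0.98 on these arrays.

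By limma, 4 of 12635 genes passed at 6 h and 1039 had an unadjusted p below 0.05, with 14.4% of genes not overlapping between the groups against 10% by chance. The count depended on single arrays and on the probe set rule: it was 18 without vehicle replicate 2, 1 without 6 h replicate 2 and 0 without any other array of these groups, 79 with the mean of a gene's probe sets, and 196 where any probe set of a gene could pass, because 179 second probe sets fell and 5 rose.

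At 16 h the change was broad, and 5405 of 12635 genes differed from vehicle. HMOX1 rose 104-fold (log2 signal 10.79 ± 0.09 against 4.09 ± 0.02, SD, log2 change 6.70 ± 0.14 SE, adjusted p = 1.1e-10, n = 3 per group). LAMP3, a lysosomal membrane protein gene at background on the vehicle arrays, rose at least 13-fold, and GPAT3, an enzyme of glycerolipid synthesis, rose 19.6-fold (4.29 ± 0.16). FOS rose 17.5-fold (4.13 ± 0.16), GEM 12.5-fold (3.65 ± 0.14) and EID3 12.2-fold (log2 SE 0.14). The largest falls were in SLC45A3, which encodes the prostate protein prostein, 7.42-fold (log2 change -2.89 ± 0.08 SE, adjusted p = 7.1e-10), and KLK4, a prostate kallikrein, 6.42-fold (-2.68 ± 0.09). SAMD1, CTXN1, MT1G and ATN1 fell 6.29-fold, 4.86-fold, 4.68-fold and 3.81-fold.

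**Figure D2:**
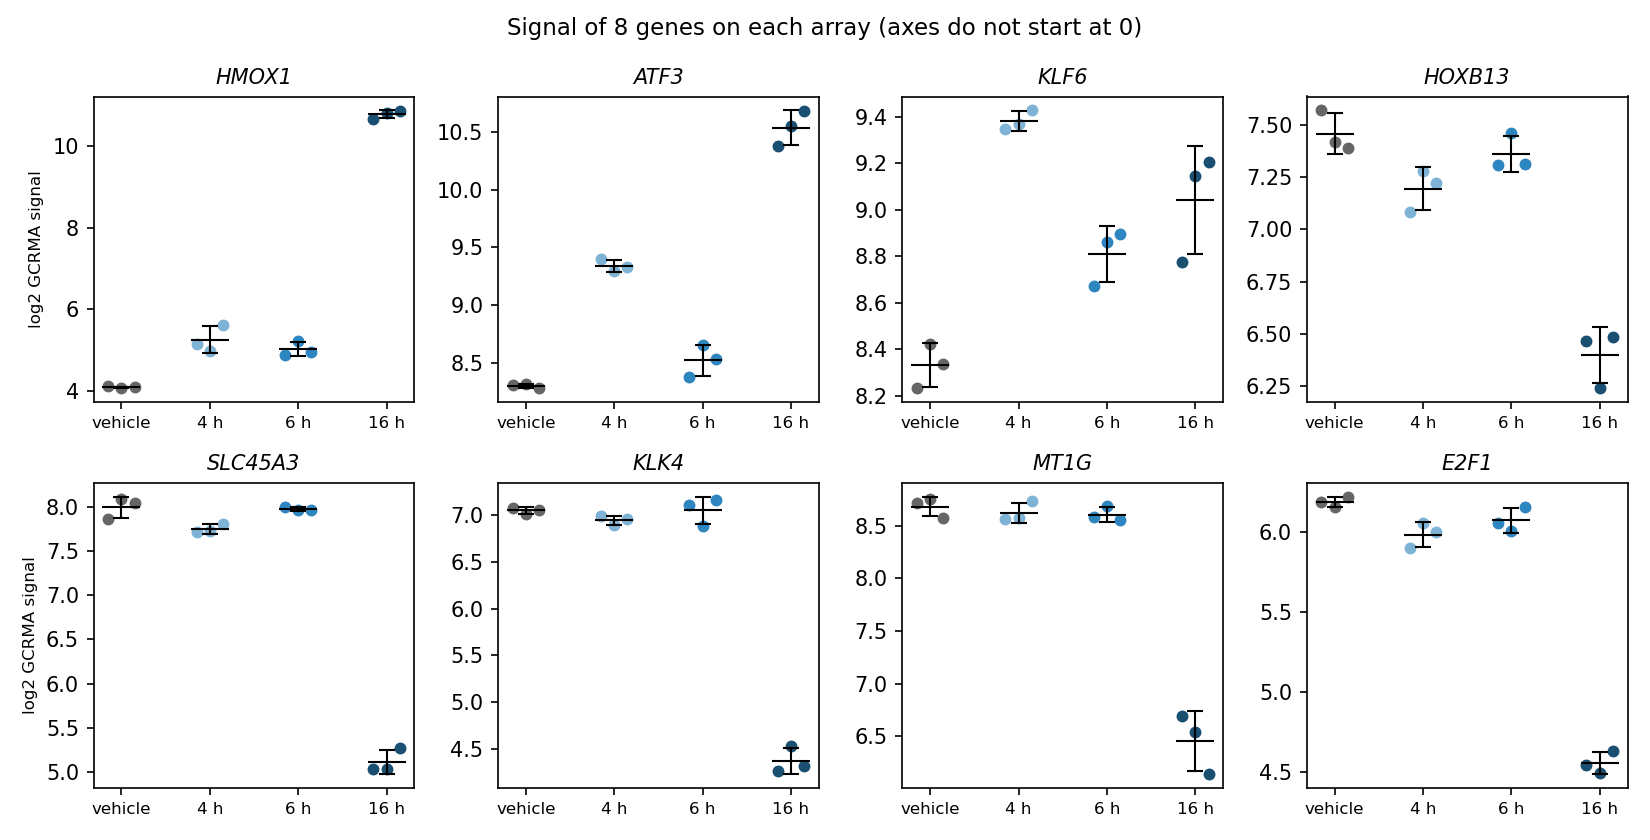
Log2 GCRMA signal of 8 genes on each array, by group; points are arrays (n = 3 per group), horizontal lines are means and bars are SD, and the axes do not start at 0. HMOX1 goes from 4.09 on vehicle arrays to 5.25 at 4 h, 5.02 at 6 h and 10.79 at 16 h, and KLK4 from 7.05 to 4.37 at 16 h.

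Stress-response lists rose at 16 h. All 34 tested amino acid and ATF4 stress genes rose (34 adjusted over the list alone, median log2 change 0.85, camera adjusted p = 9.54e-20, and adjusted p = 0.0345 with an estimated correlation), among them SESN2 10.6-fold, DDIT4 8.37-fold, ATF3 4.7-fold and DDIT3 4.19-fold. Of 23 NRF2 antioxidant genes 19 rose and 0 fell (19 and 0 adjusted over the list alone, median 0.99, adjusted p = 3.86e-13, and adjusted p = 0.0203 with an estimated correlation), led by HMOX1, OSGIN1 at 8.75-fold, AKR1C2 at 5.59-fold and AKR1C1 at 4.85-fold. Of 25 p53 target genes 20 rose and 0 fell (20 and 0 adjusted over the list alone, median 1.06, adjusted p = 4.67e-12, and adjusted p = 0.0414 with an estimated correlation), with GDF15 up 9.11-fold, the cyclin-dependent kinase inhibitor gene CDKN1A up 8.72-fold and PLK2 up 4.78-fold. The lists share members, so their counts are not independent: SESN2 belongs to both the p53 and the ATF4 list, and SLC7A11 to both the ATF4 and the NRF2 list. Of 24 endoplasmic reticulum chaperone genes 18 rose and 1 fell (20 and 1 adjusted over the list alone, median 0.29, adjusted p = 1.83e-05, and adjusted p = 0.0103 with an estimated correlation), with DNAJB9 up 2.68-fold, SEC24D up 2.18-fold and HERPUD1 up 1.72-fold, and HSP90B1 down 1.8-fold. Under median centring 11 rose and 1 fell.

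Further lists rose whose calls were lost with an estimated correlation. Of 31 immediate early genes 25 rose and 1 fell (25 and 1 adjusted over the list alone, adjusted p = 1.53e-12, and adjusted p = 0.0727 with an estimated correlation), with FOS, EGR3 at 8.3-fold, NR4A2 at 6.52-fold and EGR1 at 5.61-fold as the largest. Of 31 hypoxia-response genes 21 rose and 3 fell (22 and 3 adjusted over the list alone, adjusted p = 5.9e-07, and adjusted p = 0.163 with an estimated correlation), led by DDIT4, ADM at 6.44-fold, ANKRD37 at 5.68-fold and the histone demethylase gene KDM3A at 3.06-fold. Of 10 aryl hydrocarbon receptor targets 8 rose and 0 fell (8 and 0 adjusted over the list alone, adjusted p = 3.06e-06, and adjusted p = 0.0564 with an estimated correlation), including CYP1B1 at 10.2-fold, TIPARP at 5.95-fold, NQO1 at 3.27-fold and CYP1A1 at 3.03-fold. In this list NQO1 is shared with the NRF2 list, and SLC7A5 and STC2 with the ATF4 list. Of 27 autophagy and lysosome genes 11 rose and 0 fell (11 and 0 adjusted over the list alone, adjusted p = 0.00743, and adjusted p = 0.315 with an estimated correlation), among them GABARAPL1 at 4.17-fold, MAP1LC3B at 2.53-fold, SQSTM1 at 2.37-fold and FLCN at 2.06-fold. Under median centring 10 rose and 2 fell. Of 20 heat shock genes 10 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.012, and adjusted p = 0.315 with an estimated correlation), with DNAJB4 up 2.28-fold, HSPB8 2.25-fold, HSPA13 2.22-fold and HSPA6 at least 1.75-fold. The call was lost with the 75th percentile filter (0.0728), the mean of probe sets (0.31) and probe sets outside the _s_at and _x_at classes (0.312). Of 12 circadian clock genes 9 rose and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 0.0251, and adjusted p = 0.297 with an estimated correlation), with NFIL3 up 5.21-fold, BHLHE41 2.98-fold and RORA 2.27-fold, and DBP down 1.85-fold. The call was lost with the 75th percentile filter (0.0782) and the mean of probe sets (0.123). The 5' ACTB control signal was lower by 1.38 and the 18S ribosomal RNA control signal higher by 1.43 on the arrays in which these lists rose.

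Cell cycle lists fell at 16 h. Of 33 S phase and replication genes 27 fell and 1 rose (28 and 1 adjusted over the list alone, median log2 change -0.51, camera adjusted p = 2.87e-15, and adjusted p = 0.00095 with an estimated correlation). E2F1, a transcription factor of the G1 to S transition, fell 3.09-fold, the helicase subunit gene MCM7 2.08-fold, UHRF1 1.97-fold and GINS2 1.93-fold. Of 38 mitosis genes 31 fell and 0 rose (33 and 0 adjusted over the list alone, median -0.42, adjusted p = 7.46e-15, and adjusted p = 0.0103 with an estimated correlation), with PLK1 down 2.1-fold, TPX2 1.9-fold, CENPA 1.69-fold and BIRC5 1.69-fold. These falls were measured on arrays whose 5' ACTB control signal was lower by 1.38.

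Of 29 androgen-induced genes 16 fell and 5 rose (18 and 5 adjusted over the list alone, median log2 change -0.28, adjusted p = 1.49e-05, and adjusted p = 0.0727 with an estimated correlation). SLC45A3, KLK4 and the prostatic acid phosphatase gene ACP3, down 2.87-fold, were the largest falls, and the prostaglandin receptor gene PTGER4 rose 4.23-fold. Of 9 metallothionein and metal-response genes 6 fell and 2 rose (6 and 2 adjusted over the list alone, adjusted p = 2.87e-05, and adjusted p = 0.0716 with an estimated correlation). MT1G, MT1F, MT1X and MT1H fell 4.68-fold to 3.06-fold, each on an _x_at probe set that can bind several of these near-identical transcripts. Of 15 fatty acid synthesis genes 8 fell and 2 rose (8 and 2 adjusted over the list alone, adjusted p = 0.00726, and adjusted p = 0.214 with an estimated correlation), with FASN down 3.33-fold, SREBF1 2.84-fold and SCD 1.48-fold, and ME1 up 3.45-fold. Of 21 cholesterol synthesis genes 7 fell and 2 rose (7 and 2 adjusted over the list alone, adjusted p = 0.0251, and adjusted p = 0.288 with an estimated correlation), with SREBF2 down 1.78-fold, TMEM97 1.38-fold and MVK 1.25-fold, and STARD4 up 1.27-fold. Under median centring 10 fell and 0 rose, and the call was lost without 16 h replicate 1 (0.0645), with the 75th percentile filter (0.0523) and with probe sets outside the _s_at and _x_at classes (0.0528). Of 39 oxidative phosphorylation genes 20 fell and 0 rose (20 and 0 adjusted over the list alone, adjusted p = 1.14e-05, and adjusted p = 0.163 with an estimated correlation), none of the named ones by more than 1.36-fold: SDHA, NDUFA2, COX8A and ATP5MC1. Of 35 cytosolic ribosomal protein genes 9 fell and 0 rose (7 and 0 adjusted over the list alone, adjusted p = 0.00726, and adjusted p = 0.441 with an estimated correlation), RPLP2 by 1.42-fold and RPL32 by 1.23-fold. Under median centring 14 fell and 0 rose. The call was lost with the mean of probe sets (0.0531) and with probe sets outside the _s_at and _x_at classes (0.0587). With quantile normalisation 5 of these fell, 2 rose and the list's adjusted p was 0.564, the highest of its alternatives, which started at 0.00242. The 3' minus 5' ACTB difference of 4.09 and the higher 18S control signal belong to the same arrays.

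**Figure D3:**
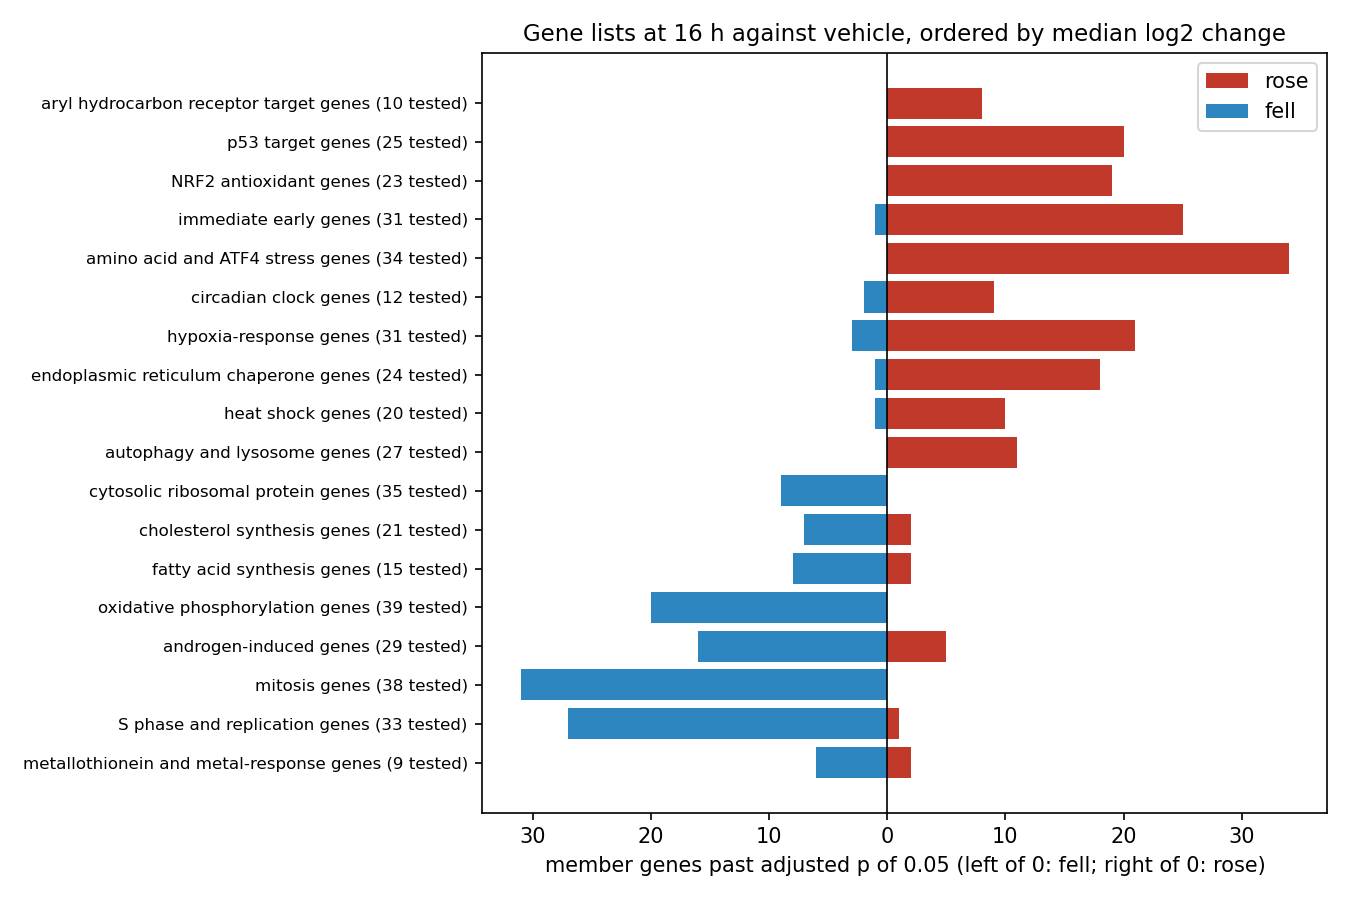
Bars count the member genes of each list that fell (left of 0) or rose (right of 0) at 16 h against vehicle (n = 3 arrays per group), for the 18 lists past camera's adjusted threshold, ordered by median log2 change. All 34 amino acid and ATF4 stress genes rose, and 31 of 38 mitosis genes fell.

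The other 11 lists did not pass at 16 h, with a lowest adjusted p of 0.162, although single members changed. Of 16 neuroendocrine and neuronal genes 4 rose and 7 fell (5 and 7 adjusted over the list alone, adjusted p = 0.379, median 0.08 with a test direction of down), with SCG2 up 1.76-fold and DDC down 1.5-fold, while 2 rose and 7 fell under the other scalings. Its median was -0.01 under median centring. Of 20 luminal and epithelial genes 5 rose and 4 fell (adjusted p = 0.6), including ELF3 up 2.87-fold and KRT19 down 1.99-fold, against 3 and 4 under median centring, and of 8 basal and mesenchymal genes 2 rose and 1 fell (adjusted p = 0.99), including FN1 up 1.66-fold and VIM down 1.26-fold, the median of 0.02 turning to -0.07 under median centring. Of 40 ribosome biogenesis genes 15 rose and 4 fell (adjusted p = 0.162), with UTP15 up 1.69-fold and LYAR down 2.02-fold, against 12 and 6 under median centring. Of 11 Wnt targets 2 rose and 3 fell (adjusted p = 0.162), with AXIN2 up 1.36-fold and SOX4 down 1.45-fold, against 1 and 3 under both other scalings. Of 11 NF-kappaB targets 2 rose and 4 fell (adjusted p = 0.282), with CXCL8 up 1.74-fold and NFKBIA down 2.19-fold. Of 16 TGF-beta and BMP targets 7 rose and 2 fell (adjusted p = 0.454), with BMP2 up 1.79-fold and PMEPA1 down 1.74-fold, against 5 and 3 under median centring, and TGIF1 rose 3.95-fold on an _s_at probe set while its brightest probe set outside that class gave -0.19 (adjusted p = 0.104). Of 16 interferon-response genes 3 rose and 2 fell (adjusted p = 0.548), with ISG20 up 3.63-fold and OAS3 down 1.92-fold, but 2 rose and 4 fell under median centring and 3 and 3 with quantile normalisation. Of 8 fibroblast genes 3 rose and 2 fell (adjusted p = 0.918, median -0.08 and mean 0.38), among them COL1A1 up 4.15-fold and LUM up 2.38-fold. None of the 3 leukocyte or 4 endothelial genes tested passed (adjusted p = 0.548 and 0.778).

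Of the 18 lists past camera's threshold at 16 h, 6 held with an estimated correlation: amino acid and ATF4 stress, NRF2 antioxidant, p53 target, endoplasmic reticulum chaperone, S phase and mitosis genes. By fry 25 of the 29 lists moved on balance one way. By limma, 3279 genes rose and 2126 fell at 16 h, 349 and 130 of them by at least 2-fold, and the groups did not overlap for 51.5% of tested genes against 10% by chance. Rises made up 60.7% of changed genes as deposited but 44.5% under median centring, which lowered the median change of all genes by 0.10, and 53.1% with quantile normalisation. Among 5913 genes with several probe sets, 2860 changed on the brightest probe set and 1549 where 2 probe sets had to pass in the same direction and none in the other.

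For ONECUT2 itself, the brightest probe set had a log2 signal of 6.71 ± 0.12 (SD, n = 3) on vehicle arrays, 6.81 ± 0.07 at 4 h, 6.71 ± 0.13 at 6 h and 7.24 ± 0.20 at 16 h, and rose at 16 h (log2 change 0.53 ± 0.10 SE, adjusted p = 0.0016). Its other probe sets differed: 1 of low signal, at 2.53 on vehicle arrays, fell to 1.86 at 16 h (adjusted p = 0.0012 over all probe sets), about the level of the unspiked controls, so the size of its fall is not exact, and those at 5.38 and 5.29 on vehicle arrays gave 0.27 and 0.41 without passing. The mean of its probe sets changed by 0.05 (adjusted p = 0.624, the highest of its alternatives). ONECUT1 lay at background on all arrays of each group, and ONECUT3 gave 2.47 on vehicle and 2.18 on 16 h arrays (adjusted p = 0.21).

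The homeobox gene HOXB13 fell 2.09-fold at 16 h (-1.06 ± 0.09, adjusted p = 2.8e-06), and its second probe set fell by 1.15. MYC was at 10.11 ± 0.06 on vehicle arrays, fell at 4 h, gave -0.22 ± 0.07 at 6 h without passing (adjusted p = 0.36), and fell 1.43-fold at 16 h (adjusted p = 9.3e-05). Its call at 4 h was lost under median centring. FOXA1, a pioneer transcription factor gene, gave -0.06, -0.09 and -0.25 at 4 h, 6 h and 16 h on its brightest probe set and passed at 16 h (adjusted p = 0.016), though not without vehicle replicate 1 (0.0532), without 16 h replicate 3 (0.0561) or in the 6 arrays alone (0.0651). Its second probe set gave -1.02, -1.33 and -1.50 and passed at 6 h and 16 h (adjusted p = 0.021 and 0.00018 over all probe sets). PEG10 gave 0.09, 0.14 and 0.02 on its brightest probe set (adjusted p = 0.68, 0.67 and 0.83) but -0.78, -1.25 and -2.01 on its second, which passed at 6 h and 16 h (adjusted p = 0.016 and 2e-06). The 6 h calls of FOXA1 and PEG10 are among the 184 second probe sets called at 6 h, of which 179 fell. That count of 184 ran from 2 without vehicle replicate 3 to 557 without vehicle replicate 2, and the cause of these falls was left undecided. On average the 179 also lay below the vehicle mean on every 4 h and 16 h array. SYP fell 1.34-fold at 16 h from a low signal of 3.71 (adjusted p = 0.012), KLK3 at 4.14 did not pass on its brightest probe set (adjusted p = 0.065) while another, at 3.94 on vehicle arrays, fell by 0.34 (adjusted p = 0.043 over all probe sets) and the remaining probe set gave 0.07, and CHGA lay at background.

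Between treatment times, 12 genes differed at 6 h against 4 h, of which 9 were lower and 3 higher. ATF3 was lower at 6 h by 1.77-fold (log2 difference -0.82 ± 0.09 SE, adjusted p = 0.0051) and EGR1 by 1.56-fold (-0.64 ± 0.06, adjusted p = 0.0051). ESRRG was lower by 1.83-fold and AASS by 1.72-fold, while SLITRK1 and CYP1A2 were higher by 1.57-fold and 1.52-fold, and PTGS1 was higher near the level of the unspiked controls. Of 31 immediate early genes 2 were lower and 0 higher (9 and 0 adjusted over the list alone), and the list was lower at 6 h (adjusted p = 2.69e-09, and adjusted p = 0.592 with an estimated correlation). Amino acid and ATF4 stress genes and cholesterol synthesis genes were also lower as lists (adjusted p = 0.00273 and 0.0273), and cytosolic ribosomal protein and oxidative phosphorylation genes higher (0.00231 each, all 4 at adjusted p = 0.652 with an estimated correlation). In limma 1187 genes had an unadjusted p below 0.05. The count of 12 fell to 0 in the 6 arrays alone and with the mean of probe sets, lay between 2 and 6 without single arrays (6, 2 and 4 without 4 h replicates 1, 2 and 3, and 4, 5 and 3 without 6 h replicates 1, 2 and 3), and rose to 59 with a trended and robust prior.

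Against 6 h, 5390 genes differed at 16 h, 3168 higher and 2222 lower, and against 4 h, 5168 differed, 3130 higher and 2038 lower. HMOX1 was 54.4-fold higher than at 6 h and 46.5-fold higher than at 4 h (log2 SE 0.14 for both), and GPAT3 and FOS were higher than at 6 h by 12.7-fold and 14.1-fold. LAMP3, at background at 4 h and 6 h, was at least 13.5-fold higher than at 6 h. SLC45A3, KLK4 and SAMD1 were lower than at 6 h by 7.31-fold, 6.43-fold and 5.73-fold. Higher genes made up 58.8% and 60.6% of these differences as deposited and 42.2% and 41.4% under median centring, which lowered the median difference by 0.10 and 0.11. Quantile normalisation gave 46.4% and 49.2%.

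Of the 58 genes changed at 4 h, 2 also passed at 6 h, both as rises. At 16 h, 30 passed again as rises and 9 as falls, and 4 passed in the opposite direction. Independent comparisons would share 10.9 rises and 2.69 falls, a value that does not allow for the vehicle arrays these comparisons share. Over disjoint arrays, at 16 h against 6 h, 40 of the 58 had the direction they had at 4 h against vehicle, 33 of them past the threshold, and 8 passed in the opposite direction. Across genes, which are not independent replicates, changes at 4 h and 6 h correlated at r = 0.56 (Spearman 0.49), those at 4 h and 16 h at 0.37 (0.33) and those at 6 h and 16 h at 0.25 (0.21). Unchanged groups simulated with independent genes and a shared simulated vehicle group gave 0.50 (0.47), a value that follows from that sharing. In them 66.7% of genes had the same sign, against 66.2% for 4 h and 6 h, 61.7% for 4 h and 16 h and 57.5% for 6 h and 16 h. Changes at 16 h were more spread across genes (SD 0.45 against 0.15 at 4 h and 0.136 at 6 h). An r below 0.50 therefore does not mean less agreement than between unchanged groups. The covariances were 0.0113, 0.025 and 0.0154 against a simulated 0.00596. Over disjoint arrays, changes at 4 h against vehicle correlated with 16 h against 6 h at r = 0.21 and changes at 6 h against vehicle with 16 h against 4 h at r = 0.07.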

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

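The tests of zinc, of dim probe sets, of a gradient between arrays and of 5' signal at 6 h were chosen only after the result was seen, and so was the rule that voids the paralog test. Differences between treatment times were collected because the groups differed past the threshold. At 6 h against 4 h, 12 genes differed: ESRRG -0.87, ATF3 -0.82, AASS -0.78, EGR1 -0.64, PTGS1 0.59, CYP1A2 0.60 and SLITRK1 0.65 on the log2 scale, and 5 not named here. At 16 h against 6 h, 5390 genes differed, with the largest differences in SLC45A3 -2.87, KLK4 -2.68, SAMD1 -2.52, CTXN1 -2.34, GPAT3 3.66, FOS 3.82, LAMP3 4.31 and HMOX1 5.76. At 16 h against 4 h, 5168 differed, with SLC45A3 -2.65, KLK4 -2.58, SAMD1 -2.35, MT1G -2.17, FOS 3.47, GPAT3 3.85, LAMP3 4.17 and HMOX1 5.54. LAMP3 was at background at 4 h and 6 h, so its differences are not exact.

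Of the genes changed at 4 h, 4 passed in the opposite direction at 16 h. CYP1A2 went from -0.76 to 0.96 (16 h against 4 h 1.72), IGFBP3 from -0.58 to 0.56 (1.14), INSIG1 from 0.52 to -0.26 (-0.77) and MAT2A from 0.49 to -0.28 (-0.77). Among the lists, endoplasmic reticulum chaperone genes were lower than vehicle at 4 h and 6 h and higher at 16 h (camera adjusted p of the difference 9.56e-08 for 16 h against 4 h and 4.72e-08 for 16 h against 6 h, and 0.00397 and 0.00325 with an estimated correlation, while the call at 4 h was at 0.242 with it). Cholesterol synthesis genes were higher at 4 h and lower at 16 h (0.00036 for 16 h against 4 h, and adjusted p = 0.109 with an estimated correlation), and with it the calls at 4 h and 16 h were lost too (0.731 and 0.288). Probe sets without a gene name or with several were outside the gene tests, and 1518 of 4598 of them changed at 16 h, 1016 up and 502 down, a signal in data not otherwise described.

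For each comparison, the 6 arrays were also divided in all 10 ways into 3 and 3. The real grouping was the only 1 of 10 to call as many genes in each of the 6 comparisons, and the highest other count was 2 at 4 h and 0 in the others. These 10 splits are too few for a share under 0.05.

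The broad change at 16 h could come from array scaling, from loss of signal toward the 5' end of transcripts, or from the treatment. Median centring put falls in the majority (2422 rises and 3024 falls), while quantile normalisation kept rises there (2944 and 2601). Rescaling the arrays did not lower the number of changed genes, the lower of the counts under quantile normalisation and median centring being 5446. The deposited values were already normalised between arrays, and these rescalings moved the median change by only -0.04 and -0.10. The test could therefore hardly lower the count, and distortion by the original normalisation stays open. For genes that fell at least 2-fold, 54.5% of second probe sets (60 of 110) also fell and 11 were called as rises, and for genes that rose at least 2-fold, 66.8% (197 of 295) also rose and 2 were called as falls, shares that lay between the bound set beforehand for this cause and the bound set against it. Loss of signal lowers values, so the share for rises does not test it as a direct cause. A second probe set is the dimmer one by definition, so a missing call can also come from low signal. Among all changed genes 40.2% of second probe sets were called in the same direction and 402 (8.14%) in the opposite one, so loss of 5' signal stays open for part of the change. The 3' minus 5' difference at 16 h was higher than vehicle by 1.28 for ACTB but only by 0.04 for GAPDH. The vehicle arrays have no matched time, and the titles of the 16 h arrays lack a code element that all other titles carry. Time in culture and whatever that element marks were therefore not testable either.

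The falls of second probe sets at 6 h, 179 of 184 called (2 called without vehicle replicate 3 and 557 without vehicle replicate 2), could come from noise in dim probe sets, from a gradient in RNA or labelling between arrays, or from loss of 5' signal. They were not particular to 6 h. The mean change of the 179 ran from -0.47 to -0.68 on 4 h arrays, -0.83 to -0.99 at 6 h and -0.86 to -0.91 at 16 h. Single vehicle arrays ran from -0.26 to 0.26 around their mean. The same vehicle arrays served to choose these probe sets and enter every comparison with vehicle, so their part cannot be separated. Noise near background is not a sufficient explanation, since 94.8% of the called second probe sets with a signal of at least 6 (55 of 58) also fell. The contrast of replicate 1 against the others correlated with the 6 h change at r = -0.23 within the 4 h arrays and -0.10 within the 16 h arrays, which left a gradient undecided. The ACTB 3' minus 5' difference was higher than vehicle by 0.22 at 6 h and that of GAPDH differed by -0.05, which left 5' loss undecided by the bounds set. The ACTB difference departed from vehicle by -0.13 at 4 h and 1.28 at 16 h, where these probe sets were also low.

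The fall of metallothionein genes at 16 h could reflect signal shared between near-identical paralogs or less available zinc. No gene (0) had a falling metallothionein probe set outside the _x_at and _s_at classes, which was the outcome set beforehand for shared signal, but only 1 such probe set lay above the unspiked controls on every vehicle array, so the test had almost nothing that could fall. After that value was seen the test was treated as void, and shared signal stays open. Less zinc should lower SLC30A1, a zinc exporter gene, which instead rose by 1.01. Whether 1 or several paralogs fell was not resolved.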

How the results depend on the processing

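A fit without the 16 h arrays, the count that required 2 probe sets and the correlations over disjoint arrays were chosen after seeing the data. All changes in direction or number below are given as values, and the cause was not tested unless stated. The number of changed genes at 16 h stayed within 1.5 times of 5405 in every alternative over all genes (4488 to 6610), while among genes with several probe sets 2860 changed on the brightest and 1549 by the separate rule that required both probe sets. At 4 h the count of 58 became 90 with the 75th percentile filter, 136 with trend and robust and 89 with array weights, and 25 to 42 when 1 array was left out. At 6 h the count of 4 became 2 with median centring, 0 with no filter, 79 with the mean of probe sets, 196 with all probe sets, 63 with trend and robust, 10 with array weights and 0 with 2 groups only, and 0 to 18 when 1 array was left out. At 6 h against 4 h the count of 12 became 26 with median centring, 0 with the mean of probe sets, 59 with trend and robust, 33 with array weights and 0 with 2 groups only, and 2 to 6 when 1 array was left out. Lists past the threshold went from 6 to 0 at 4 h, from 3 to 1 at 6 h and from 18 to 6 at 16 h with an estimated correlation, and to 2 at 4 h and 1 at 6 h with fry. PEG10 turned to -0.55 at 6 h and -1 at 16 h with the mean of probe sets, because its second probe set fell, and TGIF1 at 16 h turned to -0.19 on a probe set outside the _s_at and _x_at classes. The agreement r over all genes, 0.56 for 4 h and 6 h, 0.37 for 4 h and 16 h and 0.25 for 6 h and 16 h, ran from 0.50 to 0.65, 0.33 to 0.43 and 0.19 to 0.33 when 1 array was left out. Among genes called in at least 1 comparison r was 0.80, 0.48 and 0.35, which has no value to set it against because these genes were selected by their changes. Of the genes named as changed at 16 h, 108 kept their call whichever array was left out and 8 did not, and 105 kept it in every other alternative that tested them and 11 did not. At 4 h 11 and 14 of 24 kept it, and at 6 h 0 and 0 of 4. Alternatives in which a gene was not tested were passed over in these counts. At 16 h, for example, the 75th percentile filter tested 86 of the 119 named genes that passed the main filter. With the replicate block the counts were 84 at 4 h, 5696 at 16 h and 4 at 6 h, of which 1, QRSL1, was shared and 0 were rises, where 3 of the 4 were rises without it. GDF15, MAT2A and PTGS1 had adjusted p of 0.0548, 0.0549 and 0.0552 with the block. Deviations from the group means correlated at 0 to 0.24 between arrays with the same number, 5 of 18 pairs being above 0.1, and at -0.19 to 0.13 between other numbers, and 7 of 12 arrays correlated best with their own number. The numbers thus share some structure, but not every pair was above 0.1, and the labels do not say that a number marks a shared culture or day, so the block was kept as an alternative. A fold from or to a signal near that of the unspiked controls, at most 2.28 on any array, is not exact.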

Other observations

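The analysis of gene families by symbol was exploratory, covered 202 families and was chosen without a prior hypothesis. At 16 h the MT family had 7 falls and 0 rises among 8 genes (camera adjusted p = 1.18e-07), the KLK family of kallikreins 5 and 0 among 8 (0.00179) and the MCM replication helicase family 7 and 0 among 11 (0.00212). The 9 metallothionein probe sets found to fall were all of the _x_at or _s_at classes, which can bind several related transcripts. The MT falls may therefore not be separate, and the family overlaps with the metallothionein list. The ZNF family of zinc finger genes had 167 rises and 20 falls among 401 (0.00212), and 141 and 33 under median centring, and the DUSP phosphatase family 12 rises and 1 fall among 21 (0.00717). At 4 h the KLF family was shifted upward with 2 rises among 13 (0.000246), the ARID family upward with 0 of 8 past the threshold (0.0226), and the MRPL family of mitochondrial ribosomal proteins downward with 0 of 49 past it (0.0051). With an estimated correlation none of these passed, the lowest adjusted p being 0.379.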
